A study of Mus musculus with 24 samples.

How the data were processed

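The samples were 24 RNA-seq libraries from bone marrow macrophages of MK2 wild-type and knockout mice of the C57BL/6N strain, with 6 libraries for each combination of genotype and state. Per the labels' protocols, marrow cells were grown with M-CSF at 10 ng/ml, replated on day 7, and left unstimulated or given IL-4 at 10 ng/ml for 24 h. Libraries were made with a Kapa Hyperprep kit from total RNA and read as 40 bp single ends, per the labels' protocols, and whether strand was kept is not given in the sources used here. Where genes overlap or have near-identical copies, reads of this length may have been split between them by the authors' counting, so values of such genes are uncertain.

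The authors deposited a table of expected counts per gene, rounded to whole numbers. The submitters' processing notes name CASAVA 2.8.0, RSEM 1.3.0, Bowtie2 2.3.4.1, edgeR and the mouse build mm10, with no order or settings. The authors also deposited a table that its name gives as GETMM values, a signal scaled for gene length and library. In the files, each GETMM value equals the expected count multiplied by 1 factor for the gene and 1 factor for the library, checked on 13047 genes above 0 in every library. Both tables hold 54429 gene symbols, of which 53775 were found in the annotation's gene names, and the remaining symbols held 0.182% of the counts. Columns were matched to samples by the names in the labels, and 0 columns were left unmatched.

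Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 12797 genes and 99.8% of the counts. Libraries were scaled by TMM, and scaled counts (CPM) in the text use these library sizes, except for summed levels of marker lists and shares of counts, which use the total count. Differences were tested with edgeR 4.0.16 in R 4.3.3, by the robust quasi-likelihood test (glmQLFit and glmQLFTest), in 1 fit over the 4 groups with no covariate. Adjusted p-values are Benjamini-Hochberg over all genes tested, 0.05 was the threshold, and no limit on fold change was set. Standard errors (SE) of log2 fold changes were taken from the fold change and the F statistic. The 5 contrasts were IL-4 in wild type, IL-4 in knockout, knockout without IL-4, knockout with IL-4, and the difference between the IL-4 responses. The design, the lists and the alternatives were fixed before the data were examined.

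Total counts ranged from 7893809 to 13492507 per library. Intervals of summed counts cover counting error only, since PCR reads are not independent molecules. For genes with 3 or fewer counts in a group, a ratio of summed counts is given with an exact binomial 95% interval, and a group with 0 counts is set at 3 counts over the group. Pairs of libraries within a group differed by at least 2.66 in chi-square per degree of freedom, more than sampling noise, so no pair was taken for 1 library deposited more than once, which does not show that they came from separate cultures or animals.

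In total 26 gene lists were fixed: alternative activation by IL-4, classical activation, angiogenic factors, AU-rich targets of MK2 and tristetraprolin, members of the p38 and MK2 pathway, immediate early genes, interferon-stimulated genes, MHC class II, cell cycle, cholesterol synthesis, glycolysis and hypoxia, fatty acid oxidation and uptake, chemokines and their receptors, extracellular matrix and adhesion, heat shock and stress, macrophage identity, sex-linked genes, and markers of neutrophils, T and NK cells, B cells, erythroid cells and megakaryocytes, mast cells with basophils and eosinophils, dendritic cells, osteoclasts, stromal cells with fibroblasts, and endothelium. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated from the data. Ccn1 was looked up under its older symbol Cyr61, and Ahsp was not found among the symbols.

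The genes named were Mapkapk2 first, then for each contrast the 10 largest rises and 10 largest falls in log2 fold change past the threshold with an average log2 CPM of at least 2, leaving out predicted genes, and up to 4 members of each list. Cxcl12, Vegfa, Arg1, Retnla, Chil3 and Mrc1 were given in each contrast whatever their result. Some genes that these rules name are not reported here. A gene named for 1 genotype or state may also be given for the other, and other genes are said to be chosen after their values were seen. Coordinates are from GENCODE M21 on the same mouse build. The alternatives, whose effects are given in the closing section, were RLE size factors, DESeq2 1.42.0, no count filter, a filter of CPM at least 1 in 6 libraries, a fit of 2 groups, a term for the set of library numbers, a fit without the 3 libraries numbered apart, limma on log2(GETMM + 1), and replicate number or culture number as a block. The culture number is the number in the labels that 1 M0 and 1 M2 library of a genotype share. The 3 libraries numbered apart (wild type M0 replicate 3, wild type M2 replicate 2 and knockout M2 replicate 2) carry library numbers that do not follow on from the other 21. The stromal index is the mean log2 CPM of the stromal and fibroblast list, and fits with it as a term, with a term for the 3 libraries, or with replicates 1 to 3 or 4 to 6 alone were added after seeing the data.

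The tests were tried on simulated counts for 12797 genes with 200 genes changed by known amounts. The changed genes were drawn from those with higher mean counts, so recovery of genes with few counts was not measured. Counts were drawn independently for each gene and library, with no shared batch or culture effect. For IL-4 in wild type, 91% of 2-fold and 75% of 1.5-fold changes were recovered and 4.05% of calls were false. For knockout without IL-4, 87% and 77% were recovered and 4.65% of calls were false.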

Results

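RNA was sequenced from macrophages grown from mouse bone marrow, taken from animals with or without a functional gene for MAPKAP kinase-2 (MK2, gene symbol Mapkapk2). MK2 is a protein kinase activated by p38 that acts on proteins binding AU-rich messenger RNAs. For each genotype, 6 libraries came from unstimulated cells (M0) and 6 from cells given interleukin-4 (IL-4) at 10 ng/ml for 24 h (M2). This treatment is used to drive alternative activation. The 4 groups of 6 make 24 libraries, with total counts from 7893809 to 13492507. Levels are given as mean ± SD over the 6 libraries of a group, in counts scaled to a common library size (CPM). The series title concerns angiogenic factors made by macrophages in inflammation-driven colon cancer, so genes for such factors were given in each comparison. The labels do not say whether the replicates came from separate animals, so p-values measure the spread between these libraries, each taken as a separate unit. Each M0 library has a number in its label that 1 M2 library of the same genotype also has, and whether it names an animal is not given in the sources used here.

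Mapkapk2 (chromosome 1, 131053700 to 131097826 on mm10, minus strand) was lower in every library labelled knockout than in any labelled wild type, and its transcript was not absent. In unstimulated wild-type libraries 1 to 6 it was 100.3, 130.0, 138, 109, 116 and 119 CPM, and in wild type with IL-4 it was 120.3, 139, 118, 113, 115 and 114 CPM. In unstimulated knockout libraries it was 59.9, 57.3, 59.0, 54.7, 58.3 and 63.4 CPM, and in knockout with IL-4 it was 53.0, 60.7, 51.3, 55.1, 56.1 and 47.8 CPM. The knockout was lower without IL-4 (log2 fold change -1.01, SE 0.07, adjusted p = 1.33e-10) and with it (log2 fold change -1.15, SE 0.07, adjusted p = 2.26e-11), by edgeR's quasi-likelihood test. IL-4 left it within the replicate spread in wild type (log2 fold change 0.01, SE 0.07, adjusted p = 0.926) and in knockout (log2 fold change -0.12, SE 0.07, adjusted p = 0.269). Which part of the gene was deleted is not given in the sources used here, so reads from the remaining part of the transcript cannot be separated from full-length transcript.

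**Figure D1:**
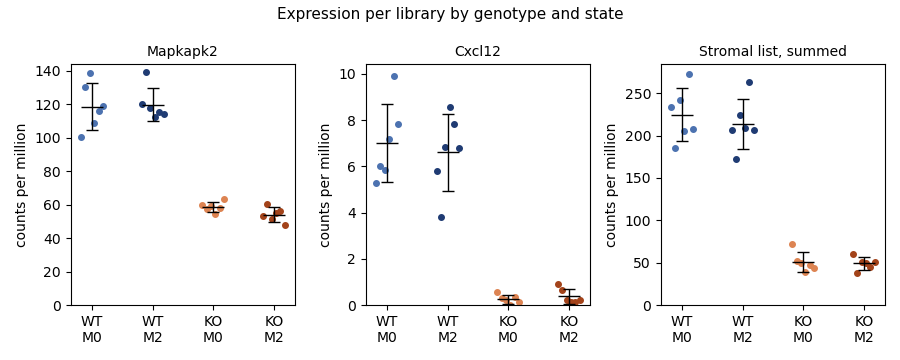
Scaled counts (CPM) in each library (points), with group mean and SD (bars), for Mapkapk2, Cxcl12 and the sum of the stromal and fibroblast marker list, in 6 libraries per group. In each panel every knockout library lies below every wild-type library of the same state.

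The first comparison asked which genes IL-4 changed in wild-type macrophages. Genes that mark alternative activation rose. Chil3, a chitinase-like secreted protein, went from 25.1 ± 2.48 CPM to 333 ± 234 CPM, and Arg1, an arginine-degrading enzyme, from 0.143 ± 0.217 CPM to 7.66 ± 1.72 CPM. With IL-4 Chil3 was 703, 497 and 366 CPM in replicates 1 to 3 and 137, 135 and 158 CPM in replicates 4 to 6. Of the 8 unstimulated Arg1 counts 5 were in replicate 6, and the ratio of summed counts was 55.8-fold with that library and 126-fold without it. Mrc1, the mannose receptor CD206, rose from 899 ± 83.2 CPM to 1519 ± 115 CPM (log2 fold change 0.76, SE 0.09, adjusted p = 1.28e-06). Retnla, a secreted resistin-like protein, had 2 counts over the 6 unstimulated libraries and 3240 with IL-4, a ratio of 1566-fold (95% exact binomial counting interval 433 to 12937). Both of these counts were in replicate 3. Against the other 5 libraries, at 0, Retnla was 813-fold higher with a floor of 3 counts over the group (lower limit of the 95% exact binomial counting interval 660). Cd14, a receptor that binds lipopolysaccharide, fell from 66.5 ± 18.1 CPM to 23.2 ± 4.74 CPM, and so did the Toll-like receptor gene Tlr2 (log2 fold change -1.63, SE 0.16, adjusted p = 2.67e-08).

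Of 12797 genes tested, 2103 changed in wild type at an adjusted p below 0.05 by edgeR's quasi-likelihood test, 1086 higher and 1017 lower, or 896 and 610 without the count filter. Among the largest rises in log2 fold change were Pdcd1lg2 (5.67), Arg1 (5.66), Apol7c (4.39), Mgl2 (4.36), Tmem26 (3.82), Chil3 (3.73) and Slc7a2 (3.26). Mgl2 encodes a galactose-binding lectin, Pdcd1lg2 the checkpoint ligand PD-L2 and Slc7a2 an arginine transporter. The sodium channel gene Scn3a had 0 counts without IL-4 and was 94.7-fold higher with it, against a floor of 3 counts over the group (lower limit of the 95% exact binomial counting interval 76.6). The potassium channel gene Kcnd3 had 3 counts without IL-4, a ratio of 185-fold (95% exact binomial counting interval 62.9 to 898), or 472-fold (84.5 to 18692) without replicate 2, which held 2 of them. The largest falls in log2 fold change were Pou2f2 (-1.86), Ctla2b (-1.73), Marcksl1 (-1.67), Clec4n (-1.63), Tlr2 (-1.63), Gpr34 (-1.55), Ifit3 (-1.54), Pcp4l1 (-1.53), Cd14 (-1.53) and Arap3 (-1.48).

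Of the 25 tested genes on the alternative activation list, 22 rose and 0 fell, with a median log2 fold change of 1.51. For alternative activation, 22 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 1.76e-27, or adjusted p = 0.00156 with an estimated correlation. Many of these genes are known from earlier work on IL-4, so the list is a check of the treatment. Of 35 cell cycle genes 29 fell, among them Ccnb2 (-0.96), Birc5 (-0.93), Cenpf (-0.90) and Top2a (-0.83). For cell cycle genes, 0 were higher and 33 lower when adjusted over the list alone, and camera gave adjusted p = 6.83e-13, or adjusted p = 0.311 with an estimated correlation. In cholesterol synthesis 16 of 23 genes rose, including Dhcr7 (0.76), Mvd (0.72) and Fdps (0.65). For cholesterol genes, 20 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 3.41e-11, or adjusted p = 0.0914 with an estimated correlation. Interferon-stimulated genes fell in 14 of 28, with Ifit3 (-1.54), Ifit2 (-1.22) and Oas2 (-1.19) as examples. For interferon-stimulated genes, 2 were higher and 17 lower when adjusted over the list alone, and camera gave adjusted p = 3.22e-05, or adjusted p = 0.381 with an estimated correlation. Fatty acid genes rose in 10 of 25, including the nuclear receptor gene Pparg (0.55) and that of its coactivator, Ppargc1b (1.07). For fatty acid genes, 14 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 1.01e-04, or adjusted p = 0.248 with an estimated correlation. Of 9 osteoclast genes 6 rose and 1 fell, with Acp5 (1.16), Ocstamp (2.13) and Atp6v0d2 (0.58). For osteoclast genes, 6 were higher and 1 lower when adjusted over the list alone, and camera gave adjusted p = 0.00678, or adjusted p = 0.164 with an estimated correlation. Of 8 genes for MHC class II presentation 3 rose, Ciita, H2-DMa and H2-DMb1. For MHC class II genes, 4 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 0.00678, or adjusted p = 0.438 with an estimated correlation. Of 21 heat shock and stress genes 7 rose, such as Hsph1 (0.37) and Gadd45b (0.66). For heat shock genes, 7 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 0.00502, or adjusted p = 0.0914 with an estimated correlation. Of these 8 lists, the alternative activation list alone stayed past the threshold with an estimated correlation.

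Angiogenic genes went both ways in wild type, 5 higher and 8 lower of 37. For angiogenic genes, 7 were higher and 9 lower when adjusted over the list alone, and camera gave adjusted p = 0.866, or adjusted p = 0.846 with an estimated correlation. Vegfa, the endothelial growth factor, fell from 26.3 ± 3.49 CPM to 19.5 ± 2.60 CPM (log2 fold change -0.43, SE 0.10, adjusted p = 0.00432). The protease gene Mmp19 (1.14) and the growth factor gene Hbegf (0.89) rose. The chemokine gene Cxcl12 was 7.01 ± 1.70 CPM and 6.61 ± 1.67 CPM, which did not pass the test (log2 fold change -0.09, SE 0.26, adjusted p = 0.864). The chemokine genes Ccl7 (2.55) and Ccl12 (2.29) rose. Fibronectin, Fn1, rose from 106 ± 28.0 CPM to 301 ± 123 CPM, and so did the integrin gene Itgax (log2 fold change 1.70). In replicates 1 to 3 alone 876 genes passed the threshold and in replicates 4 to 6 alone 1680, and the log2 fold change of Chil3 was 4.49 and 2.41, fits chosen after seeing the data.

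The second comparison asked the same question in knockout macrophages. The alternative activation genes rose here too. Arg1 went from 0.138 ± 0.123 CPM to 11.6 ± 3.24 CPM, Chil3 from 18.8 ± 6.70 CPM to 313 ± 108 CPM and Mgl2 from 0.652 ± 0.345 CPM to 45.4 ± 5.62 CPM. Mrc1 rose from 1077 ± 164 CPM to 1784 ± 223 CPM (log2 fold change 0.73, SE 0.09, adjusted p = 1.09e-06). Retnla went from 4 counts over 6 libraries to 4751, a ratio of 1238-fold (95% exact binomial counting interval 483 to 4547), or 4124-fold (739.8 to 162915) without replicate 2, which held 3 of the 4. Cd14 fell from 90.8 ± 9.68 CPM to 20.6 ± 5.50 CPM (log2 fold change -2.13, SE 0.18, adjusted p = 3.42e-09).

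In knockout 3024 genes changed at an adjusted p below 0.05 by edgeR's quasi-likelihood test, 1563 higher and 1461 lower. The largest rises in log2 fold change included Pdcd1lg2 (6.29), Mgl2 (6.06), Tmem26 (5.30), Slc7a2 (4.31) and Ear2 (3.17). Scn3a had 2 counts without IL-4 and a ratio of 310.2-fold (95% exact binomial counting interval 85.5 to 2567). They were in replicates 3 and 4, and the ratio was 517-fold (92.5 to 20468) without the one and 505-fold (90.3 to 19990.1) without the other. Kcnd3 had 0 counts without IL-4 and was 180.0-fold higher with it, against a floor of 3 counts over the group (lower limit of the counting interval 146). The largest falls in log2 fold change included Pou2f2 (-2.18), Cd14 (-2.13), Tlr2 (-1.84), Marcksl1 (-1.82), Ctla2b (-1.74), Arap3 (-1.73), Pcp4l1 (-1.70), Clec4n (-1.57) and Traf3ip3 (-1.53), and Ifit3 fell by 2.00 on the log2 scale. On the alternative activation list 22 of 25 rose, with a median log2 fold change of 1.87. For alternative activation, 23 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 3.62e-28, or adjusted p = 0.00134 with an estimated correlation. Cell cycle genes fell in 33 of 35, such as Cenpf (-1.28), Top2a (-1.17) and Plk1 (-1.17). For cell cycle genes, 0 were higher and 34 lower when adjusted over the list alone, and camera gave adjusted p = 4.15e-16, or adjusted p = 0.310 with an estimated correlation. Cholesterol genes rose in 17 of 23, such as Mvd (0.92), Fdps (0.84) and Dhcr7 (0.84). For cholesterol genes, 19 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 1.68e-09, or adjusted p = 0.115 with an estimated correlation. Interferon-stimulated genes fell in 15 of 28 while Zbp1 rose. For interferon-stimulated genes, 1 were higher and 19 lower when adjusted over the list alone, and camera gave adjusted p = 2.67e-06, or adjusted p = 0.359 with an estimated correlation. Fatty acid genes rose in 14 of 25, such as Fabp4 (0.80), Pparg (0.78) and Ppargc1b (1.17). For fatty acid genes, 15 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 2.46e-06, or adjusted p = 0.166 with an estimated correlation. Osteoclast genes rose in 6 of 9 with 1 lower, such as Ocstamp (2.84), Acp5 (1.43) and Atp6v0d2 (1.02). For osteoclast genes, 6 were higher and 1 lower when adjusted over the list alone, and camera gave adjusted p = 0.00216, or adjusted p = 0.115 with an estimated correlation.

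MHC class II genes rose in 3 of 8 in knockout. For MHC class II genes, 3 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 0.00678, or adjusted p = 0.537 with an estimated correlation. Heat shock genes rose in 9 of 21. For heat shock genes, 10 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 7.21e-04, or adjusted p = 0.0498 with an estimated correlation. Angiogenic genes were 8 higher and 6 lower of 37. For angiogenic genes, 8 were higher and 6 lower when adjusted over the list alone, and camera gave adjusted p = 0.708, or adjusted p = 0.765 with an estimated correlation. Vegfa fell from 22.2 ± 2.70 CPM to 16.7 ± 1.81 CPM (log2 fold change -0.41, SE 0.10, adjusted p = 0.00453). Cxcl12 had 15 and 22 counts over 6 libraries (log2 fold change 0.58, SE 0.53, adjusted p = 0.500). Tumour necrosis factor, Tnf, fell (log2 fold change -0.84, SE 0.11, adjusted p = 1.39e-06). In replicates 1 to 3 alone 1474 genes passed the threshold and in replicates 4 to 6 alone 2717, fits chosen after seeing the data.

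**Figure D2:**
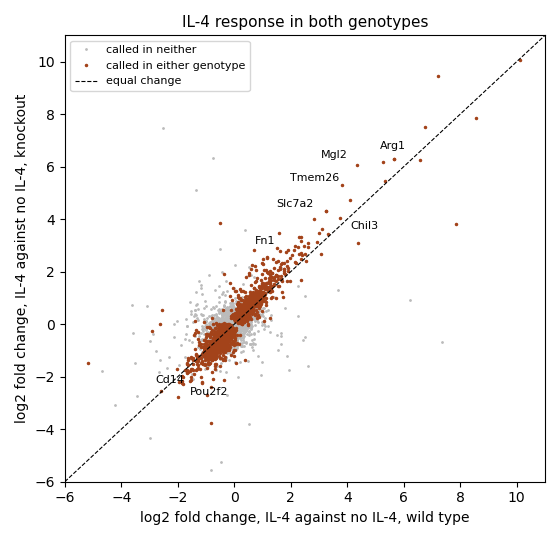
Log2 fold change with IL-4 in wild type (horizontal axis) and in knockout (vertical axis) for each of 12797 tested genes, with genes called in either genotype in red and the line of equal change dashed. Called genes lie along a common direction, and 79.8% of the 3333 called in either genotype have the larger absolute change in knockout. These genes were chosen by their calls in the same data, 2103 in wild type and 3024 in knockout. The same threshold was used in each genotype, and whether the share differs from that of equal responses was not tested. Over all 12797 tested genes, without that choice, the slope of knockout on wild type was 1.16 by the principal axis. By least squares it was 0.826. The genes are not independent, so the share is no test of a stronger response.

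The third comparison asked which genes differed between knockout and wild type without IL-4. The genes that were lower in knockout were led by collagens and other matrix genes made by fibroblasts. Col1a2, a chain of type I collagen, was 29.4 ± 7.94 CPM in wild type and 2.06 ± 1.38 CPM in knockout. Sparc, a collagen-binding matrix protein, was 22.9 ± 2.96 CPM and 2.37 ± 0.674 CPM. Cxcl12 (chromosome 6, 117168535 to 117181367 on mm10) was 7.01 ± 1.70 CPM in wild type and 0.257 ± 0.200 CPM in knockout (log2 fold change -4.73, SE 0.38, adjusted p = 1.24e-09). The summed level of the stromal marker list was also lower in knockout, at 225 ± 31.2 CPM in wild type and 50.8 ± 11.5 CPM in knockout. Vegfa did not pass the test, at 26.3 ± 3.49 CPM and 22.2 ± 2.70 CPM (log2 fold change -0.24, SE 0.10, adjusted p = 0.231). The rise with the smallest adjusted p was in Wdfy1, an adaptor of Toll-like receptor signalling, from 13.0 ± 1.91 CPM to 51.7 ± 4.48 CPM.

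In this comparison 579 genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 141 higher and 438 lower, against 236 and 487 by DESeq2 and 271 and 556 without the 3 libraries numbered apart. On the stromal and fibroblast list 14 of 15 tested genes were lower, with a median log2 fold change of -3.38. For the stromal list, 0 were higher and 14 lower when adjusted over the list alone, and camera gave adjusted p = 6.32e-45, or adjusted p = 8.57e-05 with an estimated correlation. The largest falls in log2 fold change, among genes with an average log2 CPM of at least 2, were Col12a1 (-4.07), Cyr61 (-3.85), Col1a2 (-3.85), Tnc (-3.77), Aebp1 (-3.72), Col1a1 (-3.70), Loxl2 (-3.67), Bgn (-3.61), Ctgf (-3.56) and Cyp1b1 (-3.55). The largest rises under the same limit were Wdfy1 (2.00), Dcstamp (1.86), H2-Eb1 (1.58, called in 7 of 13 alternatives), Cdkn1c (1.37), Cacna1b (1.16), Tox2 (1.11), Cd81 (1.09), Lsp1 (1.06), Vill (1.03) and Mfge8 (1.00). Dcstamp is a fusion protein of osteoclasts and Mfge8 a bridge for uptake of dying cells. On the angiogenic list 13 of 37 were lower and 2 higher, beside the lower stromal markers, including Ptx3 (-3.95), Cyr61 (-3.85) and Thbs1 (-2.36). For angiogenic genes, 5 were higher and 18 lower when adjusted over the list alone, and camera gave adjusted p = 5.82e-09, or adjusted p = 1.27e-05 with an estimated correlation. On the matrix and adhesion list 9 of 24 were lower and 2 higher, also beside the stromal markers, with Sparc (-3.27), Col4a1 (-2.76), Col4a2 (-2.59) and Fn1 (-2.27). For matrix and adhesion genes, 2 were higher and 9 lower when adjusted over the list alone, and camera gave adjusted p = 1.51e-06, or adjusted p = 1.24e-04 with an estimated correlation. Cholesterol genes were lower in 8 of 23, such as Mvd (-0.52). For cholesterol genes, 0 were higher and 12 lower when adjusted over the list alone, and camera gave adjusted p = 6.15e-07, or adjusted p = 0.207 with an estimated correlation. Interferon-stimulated genes were lower in 2 of 28, Oasl1 (-1.60) and Zbp1 (-0.85). For interferon-stimulated genes, 0 were higher and 4 lower when adjusted over the list alone, and camera gave adjusted p = 0.00287, or adjusted p = 0.605 with an estimated correlation. In replicates 1 to 3 alone, chosen after seeing the data, this list was not called (median -0.0970, camera adjusted p = 0.730).

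Of 21 AU-rich transcripts bound by tristetraprolin, a target of MK2, 3 were lower and 2 higher without IL-4, with Lif (-2.69), Ptgs2 (-2.21), Il1a (-1.26) and Cxcl2 (1.15, called in 7 of 13 alternatives). For AU-rich targets, 4 were higher and 7 lower when adjusted over the list alone, and camera gave adjusted p = 0.642, or adjusted p = 0.759 with an estimated correlation. Their median log2 fold change was 0.05 and their mean -0.20, of opposite sign. Among macrophage identity genes 4 of 22 were lower, such as C1qa (-0.69), Mertk (-0.55) and Lyz2 (-0.39), and 1 higher. For macrophage identity genes, 3 were higher and 4 lower when adjusted over the list alone, and camera gave adjusted p = 0.414, or adjusted p = 0.826 with an estimated correlation. Arg1, Chil3 and Mrc1 did not pass the test, at Arg1 (-0.05), Chil3 (-0.42) and Mrc1 (0.26), and Retnla had 2 counts in wild type and 4 in knockout. Replicates 1 to 3 alone gave 423 genes and a higher Mrc1 (0.49), replicates 4 to 6 alone 943 and the term for the 3 libraries numbered apart 902, fits chosen after seeing the data. A fit with the mean stromal marker level as a term, also chosen after, removes the difference of the stromal list by construction and gave 2 genes, and Mapkapk2 itself then did not pass (log2 fold change -1.07, SE 0.28).

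The fourth comparison asked the same with IL-4. Matrix and stromal genes were again lower. Col1a2 was 27.8 ± 4.93 CPM in wild type and 2.99 ± 1.69 CPM in knockout, and Ctgf, a matrix-associated growth regulator, 16.7 ± 2.84 CPM and 1.37 ± 0.591 CPM. Cxcl12 was 6.61 ± 1.67 CPM and 0.378 ± 0.321 CPM (log2 fold change -4.06, SE 0.36, adjusted p = 7.49e-09). The summed stromal list was also lower in knockout, at 214 ± 29.6 CPM in wild type and 49.2 ± 7.53 CPM in knockout. Vegfa was 19.5 ± 2.60 CPM and 16.7 ± 1.81 CPM, which did not pass the test (log2 fold change -0.22, SE 0.11, adjusted p = 0.351). Mgl2 was higher, at 19.8 ± 4.44 CPM in wild type and 45.4 ± 5.62 CPM in knockout (log2 fold change 1.19, SE 0.15, adjusted p = 3.97e-06). Wdfy1 was 12.8 ± 1.36 CPM and 59.2 ± 5.23 CPM (log2 fold change 2.21, SE 0.09, adjusted p = 3.84e-15).

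With IL-4 588 genes passed by edgeR's quasi-likelihood test, 193 higher and 395 lower. Of these, 71 of the higher and 303 of the lower genes also passed without IL-4, where independent lists would share 2.13 and 13.5. The M0 and M2 libraries share culture numbers, so a difference between cultures could enter both comparisons, and the overlap is no independent replication. The stromal list was lower in 14 of 15, with a median log2 fold change of -3.22. For the stromal list, 0 were higher and 14 lower when adjusted over the list alone, and camera gave adjusted p = 6.17e-46, or adjusted p = 1.48e-04 with an estimated correlation. The largest falls in log2 fold change, under the same limit, were Col12a1 (-3.88), Lox (-3.86), Cyp1b1 (-3.82), Aebp1 (-3.76), Col6a1 (-3.66), Tnc (-3.64), Cyr61 (-3.63), Grem1 (-3.63), Ctgf (-3.63) and Ltbp2 (-3.62). The largest rises were Wdfy1 (2.21), Dcstamp (1.57), Cdkn1c (1.46), Serpinb9b (1.33), Mfge8 (1.26), Mgl2 (1.19), Npy (1.08), Vill (1.07), Tnip3 (1.04) and Cacna1b (1.00). Angiogenic genes were lower in 11 and higher in 4 of 37, including Ptx3 (-3.93), Cyr61 (-3.63) and Thbs1 (-2.96), beside the lower stromal markers. For angiogenic genes, 6 were higher and 11 lower when adjusted over the list alone, and camera gave adjusted p = 1.22e-05, or adjusted p = 2.83e-04 with an estimated correlation. Matrix and adhesion genes were lower in 7 and higher in 3 of 24, with Sparc (-2.85), Col4a1 (-2.66) and Col4a2 (-2.43). For matrix and adhesion genes, 5 were higher and 10 lower when adjusted over the list alone, and camera gave adjusted p = 2.06e-04, or adjusted p = 0.00184 with an estimated correlation. On the alternative activation list 5 of 25 were higher, such as Ccl22 (1.37), Flt1 (1.18), Mgl2 (1.19) and Irf4 (1.09), and 0 lower. For alternative activation, 10 were higher and 1 lower when adjusted over the list alone, and camera gave adjusted p = 9.63e-06, or adjusted p = 0.180 with an estimated correlation. Cholesterol genes were lower in 3 of 23. For cholesterol genes, 0 were higher and 5 lower when adjusted over the list alone, and camera gave adjusted p = 8.07e-06, or adjusted p = 0.185 with an estimated correlation. Interferon-stimulated genes were lower in 3 of 28, such as Oasl1 (-2.26) and Ifi44 (-1.92). For interferon-stimulated genes, 0 were higher and 10 lower when adjusted over the list alone, and camera gave adjusted p = 5.25e-07, or adjusted p = 0.223 with an estimated correlation. In replicates 1 to 3 alone, chosen after seeing the data, camera did not call alternative activation (adjusted p = 0.539), cholesterol (0.0864) or interferon-stimulated genes (0.0930). AU-rich targets were lower in 2 and higher in 3 of 21. For AU-rich targets, 5 were higher and 3 lower when adjusted over the list alone, and camera gave adjusted p = 0.904, or adjusted p = 0.923 with an estimated correlation. Arg1, Retnla, Chil3 and Mrc1 did not pass the test, at Arg1 (0.59), Retnla (0.68), Chil3 (-0.09) and Mrc1 (0.23). With the stromal marker level as a term 2 genes passed, in replicates 1 to 3 alone 309 and in replicates 4 to 6 alone 1056, all chosen after seeing the data. In replicates 4 to 6 alone Retnla (1.64), Arg1 (1.04) and Chil3 (1.30) were higher in knockout, and Retnla also with replicate number as a block (0.86, adjusted p = 0.0241) and with a term for the library set (0.89, adjusted p = 0.0376).

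**Figure D3:**
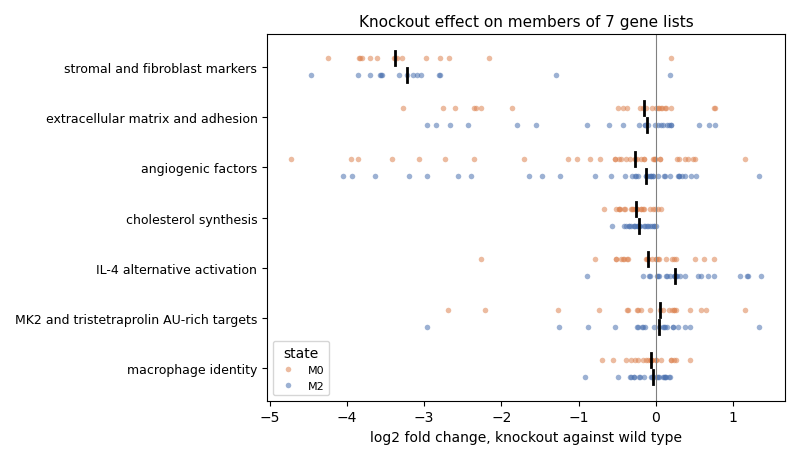
Log2 fold change of knockout against wild type without IL-4 (M0) and with it (M2) for each tested member (points) of 7 gene lists, with the median of each list as a black bar. The stromal list lies at medians of -3.38 and -3.22, while the AU-rich target list has medians of 0.05 and 0.04.

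The fifth comparison asked whether the response to IL-4 differed between genotypes. By edgeR's quasi-likelihood test 0 of 12797 genes passed an adjusted p of 0.05 for this interaction, and 390 had an unadjusted p below 0.05 where chance gives 639.9. A count below chance is no evidence of equal responses, since genes are not independent and the fit had no term for batch or culture. The interaction log2 fold changes were Arg1 0.64 (SE 0.83), Chil3 0.33 (SE 0.54), Mrc1 -0.03 (SE 0.13), Vegfa 0.02 (SE 0.15) and Cxcl12 0.67 (SE 0.59). Retnla had too few counts without IL-4, 2 and 4, for its fitted difference to be given. Genes that rose with IL-4 in wild type also rose in knockout for 962 of 1086, where independent lists would share 133. Genes that fell did so for 832 of 1017, where independent lists would share 116. No gene called in both genotypes went opposite ways. Mgl2, chosen after its values were seen, rose with IL-4 by 4.36 in wild type and 6.06 in knockout on the log2 scale. Its interaction did not pass by edgeR (log2 fold change 1.71, adjusted p = 0.406) but did by DESeq2 (adjusted p = 0.0328) and by limma on GETMM values (adjusted p = 0.0150), over a range of adjusted p from 0.0150 to 1.000 in its 13 alternatives.

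DESeq2 called 1 gene, Mgl2, and limma on the deposited GETMM values 3, Mgl2, Lrrc32 and S1pr3, named after their values were seen. With culture number as a block edgeR's test called 2, Lrrc32 (1.20, adjusted p = 0.0206) and Csf1 (1.11, adjusted p = 7.00e-04), also named after. In simulated counts for 12797 genes, genes whose response differed 2-fold between genotypes were recovered in 77% and 1.5-fold in 35%. The changed genes were drawn from those with higher mean counts, so these shares do not cover all genes tested. The simulated counts also held no shared batch or culture effect. Across the tested genes, which are not independent replicates, the log2 fold changes of the genotypes had a Pearson r of 0.740 and a Spearman rho of 0.731. The least-squares slope of knockout on wild type was 0.826 over all tested genes and 1.11 over the 3333 called in either genotype, and the slope of the principal axis 1.16 and 1.21. Whether these slopes differ from that of equal responses was not tested. Replicates 4 to 6 alone called 21 genes and replicates 1 to 3 alone 0 by edgeR's test, where 1518 and 219 had an unadjusted p below 0.05, fits chosen after seeing the data.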

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

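The tests of stromal content, library sets, expression within macrophages, flanking DNA, genetic background, a library batch, pseudogenes and depth were chosen after the results were seen. In 116 groups of 6 libraries, over 24 genes and 5 library measures, 16 had a library far from the others by Dixon's test. For independent, normally distributed values chance gives about 1 in 20. Some of these measures overlap and some rest on few counts, so the 16 cannot be set against that rate.

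Stromal markers stood out in knockout M0 replicate 1. Its stromal index was 1.42 where the next library had 0.50, its summed level 72.6 CPM where the next had 51.5, and its Col1a2 4.76 CPM where the next had 1.87. Lox in knockout M2 replicate 1 was 6.02 CPM, Sparc in wild type M2 replicate 6 was 14.7 CPM and Ctgf in wild type M2 replicate 5 was 22.3 CPM, each far from its group.

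Stromal and matrix transcripts, with Cxcl12, were lower in knockout in both states, and the stromal list shares 0 genes with the angiogenic list. The library set and the libraries numbered apart are argued against, since the median stromal log2 fold change was at or below -2.98 in replicates 1 to 3, in replicates 4 to 6 and without those libraries. Fewer stromal cells in the knockout cultures may account for it, since over 24 libraries 13 angiogenic genes called lower followed the stromal index in deviations from group means (Pearson r 0.752, p = 0.00533, or adjusted p = 0.00800 over 3 relations, with the M0 and M2 library of each culture number permuted together as the index follows that number, and r 0.549 without culture 7, the farthest from the median), and Cxcl12 did so less (r 0.620, p = 0.0403, p = 0.0671 on culture means, and r 0.320 without culture 7). Within single groups of 6, none of 12 such relations passed by exact permutation after adjustment (lowest adjusted p = 0.0667), and without the 2 libraries farthest from the median r fell below 0 in 3 (from 0.919 to -0.239 in knockout M0, and for Cxcl12 from 0.508 to -0.958 in wild type M0, among them), rose in 4 (from 0.592 to 0.990 in knockout M2, and for Cxcl12 from 0.675 to 0.932 and 0.583 to 0.880 in knockout M0 and M2, among them) and fell but stayed above 0 in 5. Lower expression within macrophages stays open, since with the stromal index as a term Cxcl12 had a log2 fold change of -0.39 (SE 1.34) and did not pass, but neither did Mapkapk2, as the index nearly parallels genotype and widens the errors.

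Wdfy1 in knockout M2 replicate 2 was 49.1 CPM, below the next library at 57.9. Wdfy1 was higher in knockout in both states and 4930402H24Rik, chosen after its values were seen, was lower, at 148 ± 8.53 CPM in wild type and 46.5 ± 2.26 CPM in knockout without IL-4. Stromal content is argued against, since with the stromal index as a term Wdfy1 kept a log2 fold change of 2.29 without IL-4 and both genes stayed past the threshold in both states. DNA flanking the targeted gene is argued against for 4930402H24Rik, which lies on chromosome 2. Wdfy1 lies 51.3 Mb from Mapkapk2 on chromosome 1, beyond the limit of 10 Mb that was set after seeing the data. The length of flanking DNA that differs between the lines is not given in the sources used here, so for Wdfy1 it is not excluded. Genetic background elsewhere in the genome may also differ between the lines, and cannot be told apart from loss of MK2 by the Wdfy1 log2 fold change of 2.00, since expression values hold no sequence.

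Wild type M2 replicate 2, numbered apart from most libraries, was the highest of its group for Mapkapk2 (139 CPM), Vwf (177 CPM) and Mfge8 (796 CPM). The 3 libraries numbered apart deviated together, with a mean correlation of deviations of 0.460 where the highest other of 216 triples from the same groups reached 0.308. A separate library or sequencing batch may account for this. Depth stays open, since 2 of the 3 totals were above those of all other libraries of their groups and the smallest, 11357234, was above all other knockout M2 libraries but replicate 3, at 13492507. A difference in how reads were assigned to pseudogenes may contribute, with a mean share of 1.26% of counts in the 3 libraries, each below the other libraries of its group, and no biological explanation was tested.

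Other single libraries stood apart. Knockout M0 replicate 2 had 5.00% of counts in mitochondrial genes, 0.300 CPM of Retnla and 80.8 CPM of Vwf. Wild type M0 replicates 1 and 4 had higher mitochondrial shares, 7.52% and 5.08%, in a group without a library far from the others by that test. Wild type M0 replicate 3 had 0.156 CPM of Retnla, wild type M0 replicate 6 had 0.576 CPM of Arg1, and wild type M0 replicate 2 had 490.4 CPM of Mfge8.

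For 4 lists the response to IL-4 differed between genotypes by camera's interaction test at the preset correlation, and for 0 lists with an estimated correlation. The median interaction log2 fold change was 0.37 for alternative activation (adjusted p = 6.31e-11, or adjusted p = 0.120 with an estimated correlation) and -0.21 for cell cycle (adjusted p = 8.04e-05, or adjusted p = 0.642). It was 0.0755 for fatty acid genes (adjusted p = 0.0135, or adjusted p = 0.513) and 0.24 for neutrophil markers (adjusted p = 0.00195, or adjusted p = 0.459). Adjusted over all genes, 0 members of these lists passed singly by edgeR's test. When adjusted over the list alone, 3 alternative activation genes were higher, Mgl2 (1.71), Fn1 (1.38) and Slc7a2 (1.05), named after their values were seen, and 0 members of the other 3 lists passed.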

How the results depend on the processing

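Fits with replicates 1 to 3 alone, replicates 4 to 6 alone, the stromal index as a term and a term for the 3 libraries numbered apart were chosen after seeing the data. Of 3622 values of named genes under an alternative, 3356 kept their sign and side of the threshold, 174 fell below it, 35 passed it, 24 changed sign with a call in 1 of the fits compared and 33 changed sign with no call in either. Of 910 values of gene lists 761, 53, 20, 9 and 67 did so, by the direction of camera's test. Genes changed by IL-4 numbered 876 in wild type and 1474 in knockout with replicates 1 to 3, and 1680 and 2717 with replicates 4 to 6, which hold as many libraries. In replicates 1 to 3 these were 506 and 370 higher and lower in wild type and 803 and 671 in knockout, and in replicates 4 to 6 903 and 777 in wild type and 1402 and 1315 in knockout. The 3 libraries numbered apart all lie in replicates 1 to 3, so differences between the sets in these counts cannot be told apart from effects of those libraries. For Chil3 with IL-4 in wild type, the difference did not rest on the library numbered apart alone. Replicates 1 and 3, at 703 and 366 CPM, were also above replicates 4 to 6, at 135 to 158 CPM. In the fit with a term for them, 4283 of 12797 genes passed the threshold for the term itself. Genes changed by knockout without IL-4 numbered 902 with the term for the 3 libraries, 423 with replicates 1 to 3, 943 with replicates 4 to 6 and 2 with the stromal index, and with IL-4 309 with replicates 1 to 3, 1056 with replicates 4 to 6 and 2 with the stromal index. Higher and lower without IL-4 were 309 and 593 with the term for the 3 libraries, 125 and 298 with replicates 1 to 3 and 385 and 558 with replicates 4 to 6, and with IL-4 321 and 466, 81 and 228 and 471 and 585. The 2 genes with the stromal index were Wdfy1 and 4930402H24Rik, while Mapkapk2 had a log2 fold change of -1.07 without IL-4 and did not pass, as the index nearly parallels genotype. Genes whose response differed between genotypes numbered 1 by DESeq2, 3 by limma on GETMM, 2 with the replicate block by culture number (Lrrc32 1.20 and Csf1 1.11 in log2 fold change, named after their values were seen) and 21 with replicates 4 to 6, against 0 in the reported fit. With an estimated correlation the lists called fell from 8 to 1 for IL-4 in wild type, 8 to 2 in knockout, 10 to 3 and 9 to 3 for knockout without and with IL-4, and 4 to 0 for the interaction, and the cause was not tested.

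With the stromal index as a term, 12 named genes called in the reported fit without IL-4 and 11 with it had log2 fold changes of opposite sign, none past the threshold, and so had 4 uncalled ones in each state. Members of the stromal list, Col1a2 0.82, Col1a1 0.88, Lox 0.13 and Dcn 0.10 without IL-4 and Col1a2 1.20, Col1a1 0.83 and Dcn 0.43 with it, and the median of that list, -0.16 with IL-4, are held near 0 as a set by construction, since the index is their mean, so their signs say nothing. The other called genes were Dcstamp -0.43, H2-Eb1 -0.92, Mfge8 -0.37, Col6a1 0.75, Grem1 1.67, Ltbp2 0.52, Lif 0.53 and Zbp1 0.67 without IL-4, and Cxcl12 0.0875, Dcstamp -0.59, Mfge8 -0.0282, Col6a1 0.12, Grem1 1.18, Lif 0.0960, Ccl8 0.80 and Ccl22 -1.74 with it. In the same fit median log2 fold changes of opposite test direction were 0.0628 for interferon-stimulated genes and -0.71 for MHC class II without IL-4, and -0.65 for MHC class II and -0.33 for osteoclast genes with it. MHC class II was -0.18 without IL-4 in replicates 1 to 3. In replicates 4 to 6 cell cycle was -0.11 and macrophage identity 0.0885 without IL-4, and cell cycle -0.39 and Chil3 1.30 with it. By camera at the preset correlation, lists called without IL-4 that were not called in replicates 1 to 3 were interferon-stimulated genes (adjusted p = 0.730) and MHC class II, and with IL-4 alternative activation (0.539), interferon-stimulated genes (0.0930), cholesterol (0.0864), MHC class II (0.938) and osteoclast genes (0.744), while for the interaction they were fatty acid genes (0.126) and neutrophil markers (0.190). Erythroid and megakaryocyte markers without IL-4 were not called in replicates 4 to 6 (0.157) or without the 3 libraries (0.0524), nor, for IL-4 in wild type, were MHC class II (0.0745) and osteoclast genes (0.0531) without the 3, a fit of the lists also chosen after seeing the data. The causes of these other changes were not tested.

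In the fits the numbers were not taken to pair the samples, since over all genes pairs sharing one did not all deviate together. This does not rule out a pairing, and the stromal index did follow the culture number (r 0.807 between M0 and M2 deviations). By culture number 8 of 12 pairs correlated above 0.1 and 7 of 12 best with their own number, where chance gives 2, a hint from the data and not from the design, and by replicate number between genotypes 4 of 12 did so above 0.1. With the replicate block 2262 and 3194 genes changed with IL-4 in wild type and knockout, 666 and 672 with knockout without and with IL-4, and 0 for the interaction, and by culture number as a block 2622 and 3446 changed with IL-4. The correlation of the IL-4 responses was 0.738 to 0.740 under the other filter and RLE size factors. At these depths genes near 3 counts per group have wide intervals.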

Other observations

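The comparison of genes near Mapkapk2 was chosen after its result was seen, and the random regroupings of the libraries were planned. Von Willebrand factor, Vwf, an endothelial and platelet protein, was expressed in all groups. It rose with IL-4 in wild type, from 54.6 ± 6.61 CPM to 136 ± 22.0 CPM (log2 fold change 1.32, SE 0.10, adjusted p = 1.11e-09), and in knockout, from 88.3 ± 3.88 CPM to 212 ± 34.4 CPM (log2 fold change 1.26, SE 0.10, adjusted p = 6.06e-10). It was higher in knockout without IL-4 (log2 fold change 0.69, SE 0.10, adjusted p = 3.88e-05) and with it (log2 fold change 0.64, SE 0.10, adjusted p = 8.79e-05). The transcription factor genes Egr2 and Klf4 rose with IL-4 in wild type, Egr2 (1.41) and Klf4 (1.65), and in knockout, Egr2 (1.68) and Klf4 (1.72). The phosphatase gene Dusp1 fell with a log2 fold change of -1.09 in wild type and -0.89 in knockout.

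Cdkn1c, an inhibitor of the cell cycle, was 15.6 ± 3.05 CPM in wild type and 40.3 ± 6.63 CPM in knockout without IL-4 (log2 fold change 1.37, SE 0.12, adjusted p = 4.16e-09). Neutrophil markers were lower in knockout without IL-4 in 2 of 10, Mmp8 (-0.85) and Csf3r (-0.34). With IL-4 neither gene passed edgeR's test, at Mmp8 (-0.31, adjusted p = 0.403) and Csf3r (-0.10, adjusted p = 0.801). For neutrophil markers, 0 were higher and 4 lower when adjusted over the list alone, and camera gave adjusted p = 5.15e-05, or adjusted p = 0.263 with an estimated correlation. Of 13 erythroid and megakaryocyte markers 2 were tested, Itga2b and Ppbp, neither of them an erythroid gene, and Ppbp was lower (-1.28). For erythroid and megakaryocyte markers, 0 were higher and 2 lower when adjusted over the list alone, and camera gave adjusted p = 0.0193, or adjusted p = 0.222 with an estimated correlation. Ppbp was also lower in knockout with IL-4 (-1.29, adjusted p = 0.0109 by edgeR's test). Of 12 endothelial markers 2 were tested, and Vwf was higher. For endothelial markers, 1 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 0.0120, or adjusted p = 0.0602 with an estimated correlation. Of 8 MHC class II genes 1 was higher, H2-Eb1 (1.58), which kept its call in 7 of 13 alternatives. For MHC class II genes, 5 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 0.00833, or adjusted p = 0.569 with an estimated correlation. In replicates 1 to 3 alone, chosen after seeing the data, the direction was reversed, with a median of -0.18 against 1.00 (camera adjusted p = 0.627). With IL-4 camera at the preset correlation called MHC class II (adjusted p = 3.61e-04) and osteoclast genes (0.0103), and neither in replicates 1 to 3 alone (0.938 and 0.744). Cell cycle genes did not pass singly, with a median log2 fold change of 0.37. For cell cycle genes, 0 were higher and 0 lower when adjusted over the list alone, and camera gave adjusted p = 2.73e-07, or adjusted p = 0.569 with an estimated correlation. In replicates 4 to 6 alone, chosen after seeing the data, the direction was reversed, with a median of -0.11 (camera adjusted p = 0.00364).

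Other lists did not pass camera's test for knockout without IL-4. The adjusted p was 0.533 for classical activation, 0.391 for members of the p38 and MK2 pathway, 0.939 for immediate early genes, 0.930 for glycolysis and hypoxia and 0.902 for chemokines. It was 0.759 for heat shock, 0.292 for fatty acid genes, 0.533 for osteoclast genes, 0.533 for alternative activation and 0.414 for sex-linked genes. Among markers of other cells it was 0.902 for T and NK cells, 0.332 for B cells, 0.725 for mast cells with basophils and eosinophils, and 0.391 for dendritic cells. Only 2 of 13, 3 of 11, 5 of 14 and 5 of 13 members of these lists were tested, in that order, so they say little about those cells.

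Chance was tested by regrouping the libraries of a comparison at random, in 100 splits with the real one included. For IL-4 in wild type 1 of 100 splits gave as many genes as the real 2103, and the highest other gave 834. For IL-4 in knockout it was 1 of 100, with 3024 and 967. For knockout without IL-4 it was 1 of 100, with 579 and 142, and with IL-4 1 of 100, with 588 and 42. Regrouping these libraries at random thus did not reach these 4 counts. It takes each library as a separate unit, and the labels do not say whether replicates came from separate animals. A difference between animals or cultures is therefore not excluded. For the interaction the real count was 0 and so was the highest other, so all 100 splits gave as many. Chance cannot be excluded for the number of lists called at the preset correlation. As many as the real 8 came from 13 of 100 splits for IL-4 in wild type (highest other 10), and as many as 8 from 21 in knockout (highest other 11). As many as the real 10 came from 6 of 100 for knockout without IL-4 (highest other 11), as many as 9 from 12 with IL-4 (highest other 11), and as many as 4 from 16 for the interaction (highest other 10).

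Of 92 tested genes within 10 Mb of Mapkapk2, 0 were called for knockout without IL-4 and 2 with it, among them Cdk18. Elsewhere 4.56% and 4.61% were called (Fisher's exact test on both sides, p = 0.0224 for fewer near the gene without IL-4 and p = 0.446 with it).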
